A study of Saccharomyces cerevisiae with 112 samples.

How the data were processed

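The series holds RNA-seq of budding yeast leaving stationary phase. Per the labels, 8 strains were grown for 72 h at 30 °C to saturation, released into fresh medium and flash frozen at 7 times: midlog growth, starvation, 5, 30 and 90 min after release, and 1 and 2 population doublings after release. Each of the 56 combinations of strain and time has 2 libraries, 112 in all, and the 7 libraries of a strain with the same replicate number are called a series here, which gives 16 series. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

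Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase I and mixed with total RNA of fission yeast (S. pombe) at 10 to 1 by mass, and poly(A) RNA was selected with oligo-dT. Libraries were made with either of a pair of stranded mRNA kits, and which library used which kit is not stated there. The spike-in was therefore added per mass of total RNA, so values on its scale describe mRNA relative to total RNA and not mRNA per cell. The submitters' processing notes name CASAVA 1.7.0 and the S. pombe build ASM294v2. The aligner, the S. cerevisiae build, the counting program and whether the counting used strand are not given in the sources used here.

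The values deposited by the authors are log2 of the median read coverage over each coding sequence, scaled by the spike-in, per the file headers and the series' design text. The deposited coverage, once taken out of log2 and divided by its smallest step in each library, fell on whole reads or on midpoints between neighbouring whole reads for 100% of the values, and on whole reads for 76.7% to 90.7%. Every library also holds 1 value off that grid, shared by 344 to 1173 genes (median 661), which stands for coverage of 0. It was set to 0 before any test; keeping it is among the alternatives. An earlier plan expected linear values, so the test of a log-scale signal was used on log2(linear value + 0.03). The pseudocount of 0.03 is the 5th percentile of the values above 0, and because of it a fold change understates the change of low genes. Genes listed at 0 throughout 1 of the groups compared are given without a fold.

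Of 6319 genes, 5694 matched a locus tag of the R64 annotation, which was used for gene names, for coding lengths (5356 genes) and for distance to the chromosome ends. No coordinates are printed, because the build of the files is not given. The 5567 genes with a value above 0.15 in at least 4 libraries were tested. Depth was read from the coverage steps. The median coverage over all 6319 genes, with undetected genes at 0, ran from 4.0 to 119.5 reads (median 52.5). The genes detected ran from 5146 to 5975, and the genes with at least 10 reads from 1508 to 5477. Precision is set by the lowest of these: values from libraries with a median under 10 reads move by single reads.

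The libraries fall into 2 processing batches by how the value for coverage of 0 was set. In 6 series (replicate 1 of wt1, wt2, Sir3_3xT7, Sir3_3xHA, sir2D and sir3D) each library had its own value, and the median gene had 4.0 to 57.0 reads (median 21.0). In the other 10 series 1 value was shared, with 9.0 to 119.5 reads (median 63.5). Both series of sir4D and of oeSir3 lie in the shared batch. The comparisons were repeated within batches. Genes called from the pooled series were picked for agreement across them. Counts of called genes that keep their direction within a batch are therefore not a separate check. Correlations between batches over all genes do not rest on that choice. Checks of depth, of trend with coding length (slopes from -0.74 to 0.42) and of the expression profile put 12 libraries in doubt; they stayed in the main results, and all counts were repeated without them.

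Tests used R 4.3.3 with limma 3.58.1, and tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Time contrasts averaged wt1 and wt2 on the spike-in scale in a fit of all 112 libraries with 56 residual degrees of freedom. Strain comparisons first averaged each series over its 7 times, after centring each library on the median gene, and had 8 residual degrees of freedom. The sir3D comparison at each time and the F tests of whether the response to release differs from wild type used single libraries on the centred scale. The tests of the tagged strains by time did too. These tests, the time contrasts and the exact permutation tests of the median gene's level treat the libraries of a series as independent. Their p-values take no account of that link. All tests were two-sided with Benjamini-Hochberg adjustment over the 5567 genes. A gene was called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1; the F tests used the adjusted p alone. Log2 changes are given ± SE. Sets of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. At the preset 284 of 798 tests passed, and with the estimated correlation 46 did.

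The groups, tests, thresholds, gene lists, all alternatives not named as added later, and the rule for named genes were fixed before the data were examined. The 39 lists cover the SIR genes, the silent mating cassettes, a-specific, alpha-specific, haploid-specific and pheromone-response genes, meiosis, ribosomal proteins, ribosome biogenesis, stress, stationary phase, trehalose and glycogen, the TCA cycle, the respiratory chain, mitochondrial ribosomes, glycolysis, gluconeogenesis with the glyoxylate cycle, fatty acid oxidation, galactose use, hexose transporters, the G1/S, G2/M and M/G1 genes, histones, seripauperins, the COS family, flocculins, maltose genes, the phosphate and iron regulons, thiamine and vitamin B6, amino acid starvation, sulfur and methionine, purines, the proteasome, autophagy, the strains' markers, genes within 20 kb of a chromosome end and the telomeric Y-prime helicases. None of the helicases passed the filter, which left 38 lists. Some list members, such as SST2, TFS1, IDH2 and SVS1, were not analysed here. The named genes are the SIR genes, the 4 members of each list with the largest called change, the 6 largest rises and 6 largest falls per comparison (for wild-type times, called on both scales and moving the same way in all 4 wild-type series; for strains, in the same direction at 5 or more of the 7 times), and the 6 smallest adjusted p of each time-course difference. A gene that this rule names at 5 min is not reported here.

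Results were recomputed, where the choice applied, with other pseudocounts, thresholds, scales, reference strains and blocks, and without each replicate. Members of near-identical families (COS, PAU, paired ribosomal protein genes, HXT6 and HXT7, and HMRA1, which has the sequence of the MATa1 gene) are uncertain, because the handling of shared reads is not given. The tests were tested on simulated data made from these libraries, with 200 of 5567 genes changed. For starvation against midlog they recovered 8%, 48%, 90% and 100% of changes of log2 1, 2, 3 and 5, with 5 false calls. For sir3D against wt2 they recovered 24%, 94%, 98% and 100%, with 7 false calls, and for the F test of the sir3D response 2%, 0%, 10% and 74%, with 0. The simulated spread between libraries was taken from the spike-in scale, while the real F test used the centred scale. Its recovery is therefore not a measure of the F test as used. The simulated data also hold no batch effect and no floor at coverage of 0.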

Results

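Messenger RNA was measured in 8 budding yeast strains followed from midlog growth through 72 h of starvation and back into growth. The strains were a pair of wild types (wt1, an S288C strain, and wt2, a relative of BY4741), deletions of SIR2, SIR3 and SIR4 (sir2D, sir3D, sir4D), strains with a tag on the C-terminus of Sir3 (Sir3_3xT7 and Sir3_3xHA, made from wt1), and a W303 strain with SIR3 under the GAL10 promoter, grown in galactose (oeSir3). Sir3_3xT7 is the Sir3_3xHA strain after a switch of the tag, so these are not independent strains. Sir2, Sir3 and Sir4 form the silencing complex of the silent mating cassettes and the telomeres. Each strain had 2 libraries at each of 7 times. Between 5146 and 5975 genes were detected per library, at a median coverage of 4.0 to 119.5 reads per gene. Replicates of a group correlated across genes at 0.81 to 0.99 (median 0.92).

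Many genes had large changes in starved wild-type cells against midlog. The glucose transporter gene HXT1 fell (-7.25 ± 0.55, log2 ± SE, adjusted p = 1.08e-17), the cysteine synthesis gene CYS3 (-7.49 ± 0.57, 8.59e-18), the cell wall gene UTR2 (-7.28 ± 0.49, 9.27e-20), the ribosomal protein gene RPS22A (-7.23 ± 0.63, 1.46e-15), INA1 (-7.16 ± 0.57, 4.52e-17) and the phosphate transporter gene PHO84 (-7.13 ± 0.63, 1.55e-15). In the same 4 wild-type libraries against 4 at midlog, HXT5, a hexose transporter of slow growth, rose by 6.93 ± 0.49 (6.41e-19), and MLS1, the malate synthase of the glyoxylate cycle, by 6.91 ± 0.46 (6.30e-20). The acetate and ammonium transporter genes ADY2 and ATO2 rose by 6.56 ± 0.51 (1.96e-17) and 6.50 ± 0.47 (1.89e-18), the stress gene DDR2 by 6.39 ± 0.57 (2.58e-15) and the lactate transporter gene JEN1 by 6.33 ± 0.49 (1.29e-17).

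The level of the median gene against the fission yeast spike-in was -0.02 ± 1.12 (log2, SD, n = 4) at midlog and -2.03 ± 0.51 at starvation. The difference of -2.02 had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and 0.0343 adjusted over the 6 time comparisons. Of 5567 genes, 244 rose and 4004 fell by limma. The median log2 change of all genes was -1.96, and after centring each library on its median gene 1256 genes were higher and 1195 lower. In the batch with separate values for zero coverage 4247 of the 4248 called genes moved in the pooled direction, and in the other batch 4248; the changes of the 2 batches correlated across genes at 0.93.

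**Figure D1:**
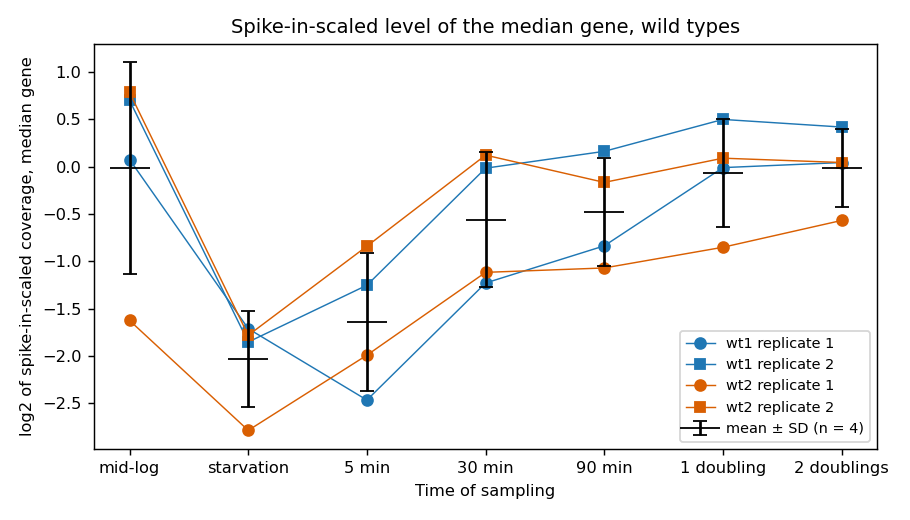
Level of the median gene on the spike-in scale (log2) in each of the 4 wild-type series against the time of sampling, with the mean and SD of the 4 libraries in black. The mean was -0.02 at midlog, -2.03 at starvation and -0.02 at 2 doublings, and wt2 replicate 1 lay at -1.63 at midlog.

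Of 18 genes of gluconeogenesis and the glyoxylate cycle, 15 rose and 1 fell at starvation (16 and 1 adjusted over the list alone), with a median of 4.40. This list passed camera at an adjusted p of 1.82e-42 and of 2.91e-04 with an estimated correlation. Among 29 stress genes 15 rose and 2 fell (15 and 2 adjusted over the list alone; median 2.42, camera adjusted p = 1.85e-26, and 0.0465 with an estimated correlation). The small heat shock gene HSP12 rose by 5.86 ± 0.83 (adjusted p = 9.68e-09), the desiccation gene SIP18 by 6.31 ± 1.16 (3.02e-06) and GRE1 by 5.79 ± 0.73 (3.53e-10). These were the 2 lists called with an estimated correlation.

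Other lists passed at the preset correlation alone. Of 103 ribosomal protein genes 101 fell (median -5.42, camera adjusted p = 5.01e-26; adjusted p = 0.237 with an estimated correlation), among them RPL23B (-7.0 ± 0.58). All 55 ribosome biogenesis genes fell (median -4.10, 9.03e-10; 0.590 estimated), including the nucleolin gene NSR1 (-6.08 ± 0.55) and the fibrillarin gene NOP1 (-5.97 ± 0.72). In glycolysis and fermentation 15 of 17 genes fell and 1 rose (median -3.84, 0.0026; 0.660 estimated), with the enolase gene ENO2 at -5.58 ± 0.59 and the pyruvate decarboxylase gene PDC1 at -5.41 ± 0.50. Of the TCA cycle's 13 genes 6 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.68, 3.73e-07; 0.310 estimated), and of 26 respiratory chain genes 9 rose (4 adjusted over the list alone; median 0.61, 1.65e-12; 0.229 estimated). The succinate dehydrogenase gene SDH2 rose by 3.52 ± 0.56 and the complex III gene QCR10 by 2.68 ± 0.47. Fatty acid oxidation had 5 of 11 genes up and 1 down (median 0.62, 1.25e-09; 0.0948 estimated), led by the thiolase gene POT1 at 4.92 ± 0.47. The stationary-phase list had 3 of 6 up and 1 down (median 1.21, 1.74e-05; 0.229 estimated), with the vitamin B6 genes SNO1 at 4.32 ± 0.53 and SNZ1 at 3.74 ± 0.58. Trehalose and glycogen genes split into 4 up and 2 down of 17 (2 and 2 adjusted over the list alone; median 0.60, 1.36e-06; 0.383 estimated).

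Cell cycle genes were lower at starvation. All 16 G2/M genes fell (median -3.12, camera adjusted p = 0.0125; adjusted p = 0.689 with an estimated correlation), with the mitotic cyclin gene CLB2 at -4.26 ± 0.70. All 8 core histone genes fell (median -3.61, 0.0048; 0.478 estimated), with HTA2 at -5.53 ± 0.68, and 22 of 23 G1/S genes fell (median -2.58, 0.0232; 0.689 estimated), with the ribonucleotide reductase gene RNR1 at -4.81 ± 0.69. Of 16 M/G1 genes 15 fell and 1 rose (median -3.09, 0.0251; 0.689 estimated), with the daughter cell wall gene EGT2 at -6.17 ± 0.62. All 31 proteasome genes (median -2.67, 0.0077; 0.689 estimated) and all 10 purine genes fell (median -2.81, 0.0378; 0.689 estimated), among them the guanine nucleotide gene IMD4 (-6.61 ± 0.59).

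Several lists had falls on the spike-in scale, and camera called none of them against other genes. The mitochondrial ribosome lost 40 of 41 genes (median -2.00, against -1.96 for all genes; camera adjusted p = 0.335), the phosphate regulon 9 of 12 (median -3.66, 0.122), the iron regulon 16 of 17 (-2.55, 0.192), the amino acid starvation genes 18 of 22 (-2.41, 0.192) and haploid-specific genes 12 of 12 (-2.32, 0.335). Sulfur and methionine genes had 11 falls and 1 rise of 17 (-1.87, 0.729), hexose transporters 4 falls and 1 rise of 8 (-2.02, 0.593), the COS family 5 falls of 8 (-1.63, 0.725), a-specific genes 3 of 7 (-1.17, 0.725), the strains' markers 4 of 9 (-0.99, 0.379), maltose genes 2 of 6 (-0.43, 0.0747) and flocculins 1 of 3 (-0.37, 0.283). Of the SIR genes (median -1.60, 0.816) SIR2 (-2.37 ± 0.48, adjusted p = 2.08e-05), SIR3 (-1.69 ± 0.60, 0.0095) and SIR4 (-1.51 ± 0.58, 0.0166) fell, while SIR1 was at -0.70 ± 0.56 (0.246); relative to the median gene the list's median was 0.36 higher. HMRA1, which has the sequence of the MATa1 gene, was at -0.89 ± 0.72 (0.255). Its value does not separate the silent cassette from the MAT locus.

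Camera placed the lists of this paragraph above other genes, though none with an estimated correlation; in some of them more members fell than rose, and in others few or none fell. Among 120 genes within 20 kb of a chromosome end 6 rose and 45 fell (median -0.92, 1.04 above the median of all genes; camera adjusted p = 2.26e-04, and 0.689 with an estimated correlation), with the alcohol dehydrogenase gene ADH6 at -6.30 ± 0.54. Pheromone-response genes had 4 falls of 13 (median -0.45, 0.0058; 0.664 estimated), meiosis genes 2 rises and 1 fall of 16 (-0.15, 9.61e-05; 0.401 estimated), thiamine and vitamin B6 genes 3 rises and 2 falls of 13 (-0.14, 0.0024; 0.392 estimated) and autophagy genes 1 rise and 3 falls of 15 (-0.35, 0.0058; 0.689 estimated). The galactose genes (1 rise and 2 falls of 8) had a median of 0.26 and a mean of -0.03 (0.0033; 0.383 estimated). Alpha-specific genes had 2 rises of 4 (median 0.83, 0.0026; 0.184 estimated), the alpha-factor genes MF(ALPHA)1 at 2.13 ± 0.56 and MF(ALPHA)2 at 1.74 ± 0.57. Seripauperins had 1 rise and 1 fall of 7 (median 0.25, 0.0037; 0.237 estimated).

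**Figure D2:**
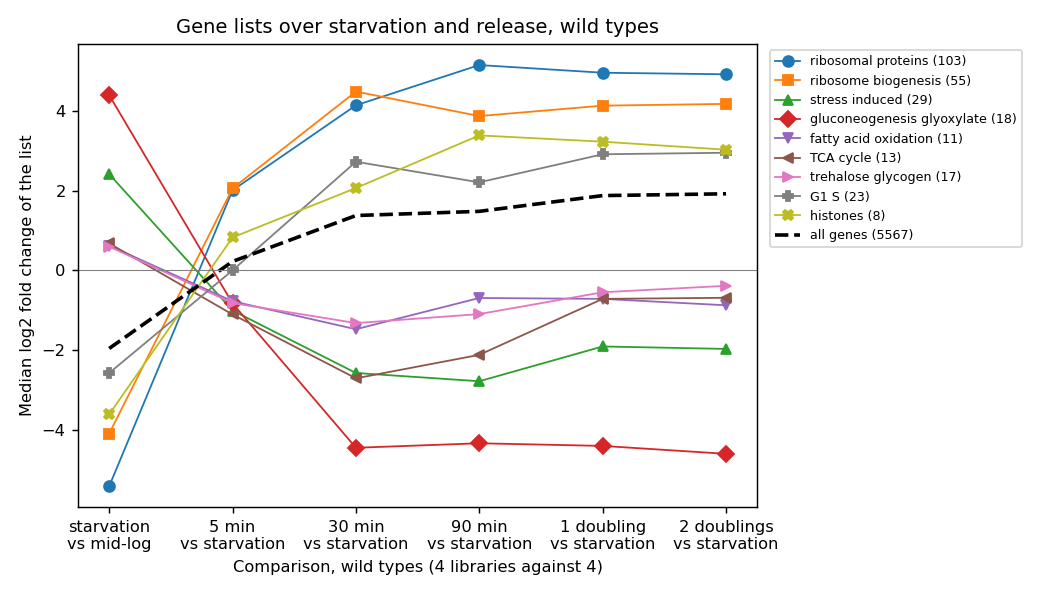
Median log2 fold change of 9 gene lists (number of genes in the legend) and of all genes (dashed) in the wild types, 4 libraries against 4 on the spike-in scale, at starvation against midlog and at each time after release against starvation. Ribosomal protein genes go from -5.42 to 2.01 at 5 min and 5.15 at 90 min, and gluconeogenesis and glyoxylate genes from 4.40 to -0.83 and -4.34.

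Changes within 5 min of release were mostly rises in the wild types. The adenine deaminase gene AAH1 rose by 6.51 ± 0.54 (adjusted p = 2.47e-15), the transporter gene AQR1 by 6.23 ± 0.66 (4.04e-11), NSR1 by 6.08 ± 0.55 (9.81e-14), the glycerol phosphatase gene GPP2 by 5.91 ± 0.47 (9.14e-16), the RNA helicase gene DBP2 by 5.40 ± 0.73 (5.39e-08) and ANS1 by 5.24 ± 0.64 (2.60e-09). The acetyl-CoA synthetase gene ACS1 fell (-3.24 ± 0.50, 1.26e-06), SHH3 (-2.73 ± 0.62, 8.93e-04), ADY2 (-2.62 ± 0.51, 1.03e-04), MLS1 (-2.62 ± 0.46, 1.47e-05) and the respiratory growth gene RGI1 (-2.50 ± 0.59, 0.0016). In all 572 genes rose and 67 fell, with a median change of all genes of 0.22; centred, 645 were higher and 444 lower. The 639 called genes kept their direction in both batches. Without wt1 replicate 2 the count was 205, and without wt2 replicate 2 it was 332.

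Of 103 ribosomal protein genes 58 rose at 5 min (81 adjusted over the list alone; median 2.01, camera adjusted p = 1.20e-24), and of 55 ribosome biogenesis genes 38 (44 adjusted over the list alone; median 2.06, 8.75e-25). RPS9A rose by 4.20 ± 0.60 (2.46e-07) and the helicase gene HAS1 by 4.0 ± 0.56 (1.49e-07). Hexose transporters had 4 rises of 8 (5 adjusted over the list alone; median 2.06, 0.0031), with HXT2 at 4.73 ± 0.73 and HXT3 at 3.13 ± 0.56, phosphate genes 6 of 12 (median 1.32, 0.0033), with PHO84 at 4.34 ± 0.63, and amino acid starvation genes 6 of 22 (8 adjusted over the list alone; median 1.18, 9.34e-04), with HOM3 at 2.57 ± 0.51. Stress genes had 6 falls of 29 (7 adjusted over the list alone; median -1.01, 2.06e-08), gluconeogenesis and glyoxylate genes 6 falls and 1 rise of 18 (7 and 1 adjusted over the list alone; median -0.83, 3.00e-09), TCA cycle genes 2 falls of 13 (5 adjusted over the list alone; median -1.11, 2.09e-06), trehalose and glycogen genes 4 of 17 (median -0.82, 1.26e-06) and fatty acid oxidation genes 2 of 11 (median -0.77, 6.04e-05). With an estimated correlation none of these lists was called; the adjusted p was 0.488 for both ribosome lists, for stress and for gluconeogenesis, 0.584 for phosphate and 0.885 for amino acids. The SIR genes lay between -0.38 ± 0.58 (SIR4) and 0.20 ± 0.56 (SIR1).

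By 30 min HXT1 had risen by 8.63 ± 0.55 over starvation (adjusted p = 1.23e-20), ANS1 by 8.33 ± 0.64 (1.62e-17), DBP2 by 7.92 ± 0.73 (1.99e-14), AAH1 by 7.89 ± 0.54 (1.67e-19), AQR1 by 7.37 ± 0.66 (1.01e-14) and the CTP synthase gene URA7 by 6.87 ± 0.52 (1.62e-17). SIP18 fell (-7.0 ± 1.16, 5.38e-07), MLS1 (-6.51 ± 0.46, 4.92e-19), ACS1 (-6.01 ± 0.50, 6.39e-16), the heat shock gene HSP26 (-5.90 ± 0.63, 4.63e-12), the CoA transferase gene ACH1 (-5.69 ± 0.48, 1.06e-15) and HXT5 (-5.54 ± 0.49, 7.82e-15). At this time 2939 genes rose and 309 fell (median of all genes 1.38; centred 1225 and 1349), and 1995 were called without wt1 replicate 2. At 90 min 3180 rose and 288 fell (median 1.48; centred 1191 and 1231), and 2270 were called without that replicate. All 3248 called genes kept their direction in both batches at 30 min, and at 90 min 3467 and 3468 of 3468 did.

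At 90 min the ribosomal genes RPS22A, RPS9B and ASC1 stood at 6.60 ± 0.63 (8.03e-14), 6.57 ± 0.65 (2.55e-13) and 6.65 ± 0.70 (1.89e-12) over starvation, HXT1 at 7.47 ± 0.55 (1.19e-17), INA1 at 7.23 ± 0.57 (7.49e-17) and AAH1 at 6.60 ± 0.54 (1.71e-16). MLS1 fell (-6.71 ± 0.46, 2.91e-19), SIP18 (-6.43 ± 1.16, 2.99e-06), HSP26 (-6.40 ± 0.63, 2.14e-13), HXT5 (-6.17 ± 0.49, 7.92e-17), ADY2 (-5.84 ± 0.51, 3.71e-15) and the membrane heat shock gene HSP30 (-5.76 ± 0.67, 4.33e-11).

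Of 103 ribosomal protein genes 101 rose at 30 min (median 4.14, camera adjusted p = 6.58e-21; 0.364 with an estimated correlation) and 102 at 90 min (5.15, 2.38e-33; 0.173 estimated), and all 55 ribosome biogenesis genes rose at both (medians 4.49 and 3.87). Gluconeogenesis and glyoxylate genes had 16 falls and 1 rise of 18 at both times (medians -4.45 and -4.34), with adjusted p of 0.0032 and 0.0012 with an estimated correlation. The gluconeogenic gene PCK1 fell at 30 min (-5.04 ± 0.46) and at 90 min (-5.72 ± 0.46). Stress genes had 21 falls and 1 rise of 29 at 30 min (-2.58; 0.0554 estimated) and 23 falls at 90 min (-2.78; 0.0170 estimated). TCA cycle genes had 10 falls of 13 at 30 min (-2.71, 2.32e-14; 0.111 estimated), among them the citrate synthase gene CIT1 (-4.70 ± 0.58), and respiratory chain genes 14 of 26 (-1.40, 7.24e-16; 0.142 estimated).

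Cell cycle lists were called by camera at different times, and at the times below none was with an estimated correlation. At 5 min none of 23 G1/S genes was called (median 0.00), and at 30 min 22 rose (median 2.73, camera adjusted p = 4.21e-04; adjusted p = 0.878 with an estimated correlation), RNR1 by 4.95 ± 0.69 (8.39e-09) and the replication clamp gene POL30 by 4.11 ± 0.49 (1.28e-10). Histones had 7 rises of 8 at 30 min (median 2.07, 0.312) and 8 at 90 min (3.39, 0.0063; 0.546 estimated). G2/M genes had 7 rises of 16 at 30 min (1.27, 0.995) and 16 at 90 min (2.97, 0.0067; 0.825 estimated), CLB1 by 5.05 ± 0.71 and CLB2 by 4.24 ± 0.70 at 90 min. M/G1 genes had 11 rises and 1 fall of 16 at 90 min (1.83, 0.772) and 15 rises and 1 fall at 1 doubling (3.42, 0.0060; 0.617 estimated), EGT2 by 6.26 ± 0.62. Relative to the median of all genes the G2/M list stood at -0.10 at 30 min and 1.48 at 90 min, and the M/G1 list at 0.35 at 90 min and 1.54 at 1 doubling. The differences between times within a list were not tested.

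The wild types at 1 and 2 population doublings after release were compared with starvation, and not with midlog. At 1 doubling INA1 stood at 7.88 ± 0.57 (adjusted p = 1.22e-18) over starvation, HXT1 at 7.61 ± 0.55, UTR2 at 7.59 ± 0.49, CYS3 at 7.54 ± 0.57, PHO84 at 7.40 ± 0.63 and the septation gene SUN4 at 6.96 ± 0.55, and SIP18 at -8.09 ± 1.16, MLS1 at -6.97 ± 0.46, HXT5 at -6.83 ± 0.49, ADY2 at -6.37 ± 0.51, ACS1 at -6.15 ± 0.50 and DDR2 at -6.03 ± 0.57. At 2 doublings the largest rises were in INA1 (7.82 ± 0.57), UTR2 (7.74 ± 0.49), PHO84 (7.56 ± 0.63), CYS3 (7.48 ± 0.57), HXT1 (7.47 ± 0.55) and SUN4 (7.02 ± 0.55), and the largest falls in SIP18 (-8.60 ± 1.16, 2.27e-09), HXT5 (-7.12 ± 0.49), MLS1 (-6.98 ± 0.46), ATO2 (-6.51 ± 0.47), ADY2 (-6.37 ± 0.51) and DDR2 (-6.30 ± 0.57). At 1 doubling 3797 genes rose and 271 fell (median of all genes 1.88; centred 1213 and 1344), and at 2 doublings 3866 and 264 (1.92; centred 1201 and 1362). All 4068 called genes kept their direction in both batches at 1 doubling, and 4129 of 4130 in each at 2.

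The level of the median gene did not differ from starvation at 5 min by the test (0.40, exact permutation p = 0.4, n = 4 per time; 0.21 without wt2 replicate 2 and 0.78 without wt1 replicate 1). It rose by 1.47 at 30 min, 1.56 at 90 min, 1.97 at 1 doubling and 2.02 at 2 doublings (exact permutation p = 0.0286 for each of these 4). SIR2 rose over starvation by 1.81 ± 0.48 at 30 min (adjusted p = 0.0011), 2.23 ± 0.48 at 90 min (7.73e-05), 2.65 ± 0.48 at 1 doubling (3.04e-06) and 2.93 ± 0.48 at 2 doublings (3.71e-07). SIR3 rose by 1.40 ± 0.60 (0.0320) and 1.83 ± 0.60 (0.0055) and SIR4 by 1.40 ± 0.58 (0.0270) and 1.59 ± 0.58 (0.0122) at the doublings, less than the medians of all genes of 1.88 and 1.92; no rise relative to other genes was found. Gluconeogenesis and glyoxylate genes had 16 falls and 1 rise at each doubling (medians -4.41 and -4.60; adjusted p = 7.28e-04 and 6.74e-04 with an estimated correlation), and stress genes had 20 and 17 falls and 1 rise each (medians -1.91 and -1.97; 0.0380 and 0.0434 estimated).

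The deletions were examined first at their targeted genes. SIR2 was listed at 0 in all 14 sir2D libraries, SIR3 in all 14 sir3D libraries and SIR4 in all 14 sir4D libraries. In wt2 the same genes were detected in all 14 libraries, SIR2 with 5.00 to 104.0 reads, SIR3 with 3.00 to 37.0 and SIR4 with 3.00 to 33.0.

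Without Sir2, Sir3 or Sir4 the MATa cells lost mRNA for mating. In sir3D the a-factor genes MFA2 (-8.38 ± 0.59, adjusted p = 3.25e-05) and MFA1 (-6.27 ± 0.58, 1.48e-04) fell against wt2, averaged over the 7 times in 2 series each. The agglutinin gene AGA2 fell (-5.43 ± 0.71, 0.0025), the alpha-factor receptor gene STE2 (-4.93 ± 0.39, 5.77e-05), the mating kinase gene FUS3 (-4.09 ± 0.37, 1.47e-04) and the G beta gene STE4 (-3.80 ± 0.24, 2.31e-05). The subtelomeric COS12 rose by 3.50 ± 0.36 (4.42e-04), the mitochondrial gene NCA3 by 2.12 ± 0.36 (0.0195), and the G1 cyclin genes CLN1 and PCL1 by 1.32 ± 0.25 (0.0427) and 1.27 ± 0.23 (0.0271). The meiotic methyltransferase gene IME4, listed at 0 in 13 of 14 wt2 libraries and detected in all 14 of sir3D, was higher (0.0023); it has an antisense partner, and strand use in the counting is not given. In all 7 genes rose and 22 fell in sir3D, and on the spike-in scale 6 and 15.

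In sir2D 5 genes rose and 24 fell, and in sir4D 8 and 31; on the spike-in scale these were 9 and 17, and 11 and 16. In sir2D MFA2 (-8.59 ± 0.59, adjusted p = 2.98e-05), AGA2 (-6.05 ± 0.71, 9.82e-04), MFA1 (-6.04 ± 0.58, 1.94e-04), STE2 (-4.88 ± 0.39, 4.41e-05) and FUS3 (-4.19 ± 0.37, 9.82e-05) fell. In sir4D MFA2 (-9.58 ± 0.59, 7.50e-06), AGA2 (-6.90 ± 0.71, 3.09e-04), MFA1 (-6.56 ± 0.58, 8.44e-05), STE2 (-5.21 ± 0.39, 2.51e-05) and FUS3 (-4.78 ± 0.37, 3.18e-05) fell, as did FAR1 (-4.38 ± 0.29, 1.14e-05), an inhibitor of the cell cycle kinase in the pheromone arrest. COS12 rose by 3.59 ± 0.36 (2.76e-04) in sir2D and 3.70 ± 0.36 (2.04e-04) in sir4D, NCA3 by 2.01 ± 0.36 (0.0283) and 1.87 ± 0.36 (0.0365), IME4 was higher in both (9.82e-04 and 0.0012), and in sir4D the polyamine transporter gene TPO2 rose by 2.44 ± 0.43 (0.0200) and COM2 by 1.45 ± 0.27 (0.0347).

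**Figure D3:**
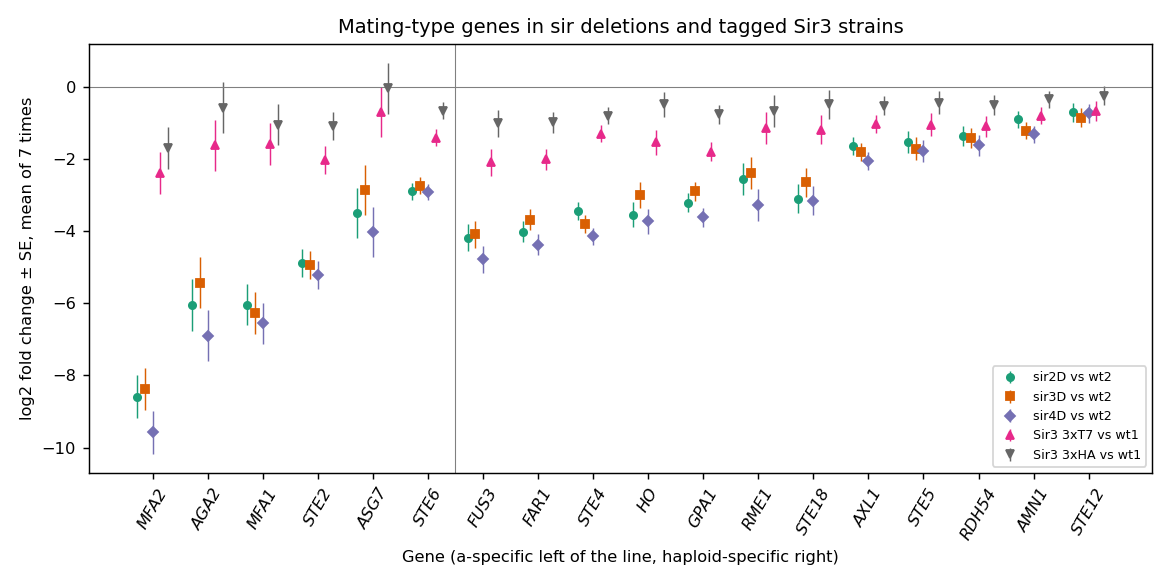
Centred log2 fold change with its SE, averaged over 7 times, of a-specific genes (left of the line) and haploid-specific genes (right) in the deletions against wt2 and the tagged strains against wt1. MFA2 lies at -8.38 in sir3D, -8.59 in sir2D, -9.58 in sir4D, -2.39 in Sir3_3xT7 and -1.70 in Sir3_3xHA.

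Of 7 a-specific genes 5 fell in sir3D, 5 in sir2D and 6 in sir4D (6 in each adjusted over the list alone, with 1 rise); medians were -4.93, -4.88 and -5.21, and camera's adjusted p with an estimated correlation was 0.0090, 0.0097 and 0.0119. The rise adjusted over the list alone is that of BAR1, which wt2 lacks. In the deletions BAR1 was detected in all 14 libraries each, with 1.0 to 18.0 reads in sir3D, 3.0 to 17.0 in sir2D and 5.5 to 28.5 in sir4D. The deletions thus differ from wt2 in BAR1 as well as in the deleted SIR gene. Whether that affects other genes was not tested. Of 12 haploid-specific genes 9, 8 and 11 fell (11, 10 and 11 adjusted over the list alone; medians -2.53, -2.83 and -3.22), at 8.52e-04, 0.0012 and 0.0012. HO, the mating-type switching nuclease, lay at -3.00 ± 0.35 (0.0011), -3.55 ± 0.35 (2.48e-04) and -3.73 ± 0.35 (1.50e-04). Of 13 pheromone-response genes 2, 2 and 3 fell (4, 4 and 7 adjusted over the list alone; medians -0.50, -0.83 and -1.14), at 0.0425, 0.0196 and 0.0215; the fusion gene FUS1 lay at -2.32 ± 0.26 (9.77e-04), -2.24 ± 0.26 (9.82e-04) and -2.67 ± 0.26 (2.12e-04). None of the 4 alpha-specific genes was called, with MF(ALPHA)1 at -0.03 ± 0.41, -0.84 ± 0.41 and -1.36 ± 0.41. HMRA1 lay at 0.31 ± 0.50, -0.27 ± 0.50 and 0.51 ± 0.50. Since MATa1 has the same sequence, these values cannot show whether the silent cassette was expressed.

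Other lists were called in the deletions at the preset correlation alone. G1/S genes had 2 rises of 23 in sir3D (3 adjusted over the list alone; median 0.31, camera adjusted p = 2.29e-07; adjusted p = 0.207 with an estimated correlation), and the COS family 1 rise of 8 in sir2D and sir4D (medians 0.43 and 0.36; 0.273 and 0.33 estimated). Ribosomal protein genes had medians of -0.37, -0.55 and -0.73 with none of 103 called (0.965, 0.560 and 0.560 estimated). In 5 replicate 1 libraries of wt2 the values varied with coding length. On the spike-in scale the median of all genes lay 0.29 (sir3D), 0.54 (sir2D) and 0.56 (sir4D) above wt2. The wt2 series themselves lay apart on this scale. The median gene of wt2 replicate 1 was below that of replicate 2 at every time, at -1.63 and 0.78 at midlog and -0.57 and 0.04 at 2 doublings. How far the offset rests on wt2 replicate 1 was not tested, so it is not taken as an effect of the deletions.

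All 29 called genes of sir3D and all 29 of sir2D moved in the pooled direction by 2-fold or more in each batch, where 1 series stands against 1, although the differences of all genes correlated between batches at 0.19 and 0.40 across genes. Both sir4D series share a batch, where all 39 did. These genes were called from the same series, so their agreement within batches is not a separate test. With a processing batch block more genes were called in sir3D and sir2D, as given further below. Counts depended on wt2 replicate 2. Without it 150 genes were called in sir3D, 202 in sir2D and 297 in sir4D; without sir3D replicate 1 or 2 the sir3D count was 18 or 16, without sir2D replicate 2 the sir2D count was 19, and without sir4D replicate 1 the sir4D count was 22.

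The deletions shared most of their called genes. Of 44 genes called in any of them, 20 fell in all 3, namely MFA1, MFA2, AGA2, STE2, STE6, FUS1, FUS3, FAR1, GPA1, HO, RME1, AXL1, STE4, STE18, PRM1, SRD1 and 4 genes without a standard name, and 5 rose in all 3, namely COS12, IME4, NCA3, YGL262W and YIR042C; the last 2 are singled out after their values were seen. By systematic name the 4 genes without a standard name lie beside other called genes. YNL146C-A lies by MFA2, YJL156W-A by FAR1, YJR087W by STE18 and YGL193C by IME4, and YGL262W lies by COS12. Strand use and the handling of shared reads are not given, so these neighbours may not count as separate genes. The falls shared by pairs numbered 20 (sir2D and sir3D), 22 (sir2D and sir4D) and 21 (sir3D and sir4D). The differences of all genes correlated across genes at 0.79, 0.78 and 0.68, with covariances of 0.168, 0.202 and 0.164. Unchanged groups against the same wt2 libraries gave 0.50 and 0.0843 in 100 simulations, which hold no batch effect. With each deletion set against a separate wt2 series the correlations were -0.01, 0.10 and 0.03 (covariances -0.0077, 0.0261 and -0.0119), and with series of the same batch set together 0.24, 0.31 and 0.29 (0.0715, 0.0912 and 0.0841). The correlation across all genes is therefore not taken as shared effects of the deletions.

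A few genes near chromosome ends were higher in the deletions. Among 120 genes within 20 kb, 3 rose in each deletion, namely COS12, its neighbour YGL262W, and YIR042C (4, 3 and 4 rises and 2, 0 and 2 falls adjusted over the list alone). List medians were 0.13 in sir3D and sir2D and -0.01 in sir4D, where the mean was 0.13 and camera's direction was up; with a processing batch block the sir4D median was 0.20 (2.80e-08), so its sign depends on the model. On the spike-in scale the medians were 0.46, 0.69 and 0.60, against 0.29, 0.54 and 0.56 for all genes, with 3, 5 and 5 rises. The adjusted p of 1.35e-04, 4.66e-05 and 0.0032 became 0.694, 0.40 and 0.560 with an estimated correlation. Without wt2 replicate 2 the medians were -0.04, -0.04 and -0.13 (0.317, 0.224 and 0.487). In the 37 genes within 10 kb, with the same 3 rises, the medians were 0.45 (1.93e-13), 0.52 (1.11e-11) and 0.38 (1.15e-09), not called with an estimated correlation (0.165, 0.219 and 0.275). Without wt2 replicate 2 these medians were 0.16 (0.0033), 0.16 (0.0069) and 0.15 (0.0227), and without wt2 replicate 1 0.92, 0.89 and 0.67. Without sir3D replicate 2 the sir3D median was 0.69, and without sir2D replicate 1 or 2 that of sir2D was 0.27 or 0.79. By distance, the 13 genes within 5 kb had medians of 0.59, 0.63 and 0.36, the 24 genes from 5 to 10 kb 0.40, 0.49 and 0.44, and the 83 genes from 10 to 20 kb 0.01, 0.04 and -0.06.

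Mating gene lists were lower in sir3D than in wt2 at each time, and all but 1 of these calls held with an estimated correlation. The a-specific list had medians of -5.20 at midlog, -2.47 at starvation, -1.59 at 5 min, -4.76 at 30 min, -5.92 at 90 min, -7.01 at 1 doubling and -6.61 at 2 doublings, with 5, 3, 2, 5, 6, 5 and 6 of 7 genes falling and 1 rising at 90 min (6, 5, 3, 5, 6, 6 and 6 falls adjusted over the list alone, and 1 rise at each time but starvation). The adjusted p was 1.06e-05, 0.0062, 0.243, 2.86e-05, 5.68e-07, 9.40e-12 and 2.18e-08 with an estimated correlation. The haploid-specific medians were -3.24, -1.22, -1.52, -1.59, -2.33, -3.01 and -3.40 (4.09e-08, 0.0062, 0.0016, 1.20e-05, 3.55e-08, 3.23e-16 and 5.84e-12), with 9, 2, 5, 6, 5, 10 and 10 falls of 12 (10, 7, 8, 10, 12, 11 and 11 adjusted over the list alone). Of all genes 33 were called at midlog (10 higher and 23 lower), 17 at starvation (6 and 11), 42 at 5 min (14 and 28), 28 at 30 min (9 and 19), 27 at 90 min (8 and 19), 28 at 1 doubling (3 and 25) and 36 at 2 doublings (6 and 30), with 2 libraries in each group. On the spike-in scale the higher and lower genes numbered 2 and 16, 5 and 1, 12 and 2, 23 and 6, 14 and 10, 3 and 16, and 3 and 20 in order of time, so that more were higher than lower from starvation to 90 min. With a processing batch block more genes were called at midlog, starvation, 5 min and 30 min, as given further below. The counts rest on few libraries. Without wt2 replicate 2 they were 947 at midlog, 344 at starvation, 275 at 5 min and at 30 min, 620 at 90 min and 95 at 2 doublings, and without wt2 replicate 1 they were 21, 5, 24, 48 and 22 at midlog, starvation, 5 min, 30 min and 2 doublings. Without sir3D replicate 1 they were 21, 2, 8, 15, 17, 18 and 20 in order of time, and without sir3D replicate 2 they were 9 at starvation, 293 at 5 min and 15 at 30 min.

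The response to release, by the F test, differed from wild type for 10 genes in sir3D, 9 in sir2D and 6 in sir4D. The counts depend on the model: on the spike-in scale they were 7, 3 and 1, and with a processing batch block 15, 13 and 10, where all genes called without it were among them. With a replicate block the counts were higher still, as given further below. In sir3D the difference in the change since starvation, sir3D minus wild type, was -3.74 at 1 doubling for the G alpha gene GPA1 (adjusted p = 3.15e-06), -5.00 for HO (4.41e-06), -4.99 for STE2 (7.49e-06), -3.22 for the a-factor transporter gene STE6 (1.11e-05) and -3.86 for FAR1 (1.68e-04), and at 5 min it was between -1.03 and 0.46 for these 5. The cohesin loader gene SCC4 was at -1.89 at 30 min (0.0346). HO, STE2, FAR1, STE6 and GPA1 were also among the 6 leading genes of sir2D and sir4D, with HO at -5.41 and -5.65 at 1 doubling (2.69e-07 and 3.13e-07). Also among the 6 were SIR2 in sir2D (7.23e-04), where it is listed at 0, and FUS1 in sir4D (0.0032). SIR2 cannot change in sir2D, so its difference only mirrors the change in the wild type. HO, STE2, FAR1, STE6 and GPA1 were themselves lower in each deletion averaged over time. How far that low level sets their differences was not tested. Without replicate 1 the sir3D count was 4 and without replicate 2 it was 29, and without replicate 2 the sir2D count was 5.

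The tagged strains, which the labels describe as having impaired Sir3 function, showed part of the deletion pattern. In Sir3_3xT7 against wt1 COS12 rose by 3.65 ± 0.36 (adjusted p = 0.0026), YGL262W by 2.87 ± 0.34 (0.0058) and YIR042C by 2.18 ± 0.24 (0.0043), IME4, at 0 in all 14 wt1 libraries, was higher (0.0261), and FAR1 (-2.01 ± 0.29, 0.0231) and GPA1 (-1.80 ± 0.26, 0.0231) fell. In Sir3_3xHA COS12 rose by 3.36 ± 0.36 (0.0060), YGL262W by 2.51 ± 0.34 (0.0221) and YIR042C by 2.03 ± 0.24 (0.0089), and no gene fell. SIR3 mRNA lay at -0.27 ± 0.32 in Sir3_3xT7 and -0.25 ± 0.32 in Sir3_3xHA, neither called. MFA2 was at -2.39 ± 0.59 (0.567) and -1.70 ± 0.59, STE2 at -2.02 ± 0.39 (0.116) and -1.10 ± 0.39, and FUS3 at -2.10 ± 0.37 (0.0859) and -1.02 ± 0.37. The called genes, 6 and 3, moved 2-fold or more in the pooled direction in each batch, while all genes correlated between batches at 0.13 and -0.22. On the spike-in scale the counts of called genes were 2 and 1. With a processing batch block more genes were called in Sir3_3xT7, as given further below. With Sir3_3xT7 replicate 2 or wt1 replicate 2 left out none was called in Sir3_3xT7 (limma), and 3 were without wt1 replicate 1. In Sir3_3xHA none was called without Sir3_3xHA replicate 1, Sir3_3xHA replicate 2 or wt1 replicate 2. With all libraries, 72 and 28 of 5567 genes had an unadjusted p under 0.05. These shares lie under 0.05, the share that strains without any difference would give on average. They are thus no sign of further changes, and the few calls do not show that the strains are alike.

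Of 12 haploid-specific genes 2 fell in Sir3_3xT7 (10 adjusted over the list alone; median -1.17, camera adjusted p = 1.50e-48, and 6.26e-04 with an estimated correlation) and none in Sir3_3xHA (none adjusted over the list alone; median -0.52, 2.28e-24; 0.0076 estimated). None of 7 a-specific genes was called in either (4 and 2 fell adjusted over the list alone; medians -1.59 and -0.67; 0.0116 and 0.0366 estimated). The COS family had 1 rise of 8 in each (medians 0.89 and 0.49; 0.0092 and 0.0206 estimated), with COS1 at 1.96 ± 0.85 and COS4 at 1.18 ± 0.47 in Sir3_3xT7, not called. Alpha-specific genes had medians of 0.47 (0.309 estimated) and 0.57 (0.0366 estimated), with none of 4 called (0 and 1 rose adjusted over the list alone). The 120 genes within 20 kb of an end had medians of 0.18 and 0.16 (3.98e-11 and 5.98e-14; 0.239 and 0.107 estimated). On the spike-in scale they were 0.06 and 0.04, against -0.10 for all genes in each, with 2 and 1 rises in place of 3 and 3. Without wt1 replicate 2 the medians were 0.07 in each, and without wt1 replicate 1 0.39 and 0.34. The 37 genes within 10 kb had medians of 0.68 (2.26e-28; 0.0225 estimated) and 0.49 (1.76e-34; 0.0160 estimated). With 1 series left out the medians within 10 kb ranged from 0.45 (without Sir3_3xT7 replicate 1) to 1.04 (without wt1 replicate 1) in Sir3_3xT7, and from 0.25 (without wt1 replicate 2) to 0.81 (without wt1 replicate 1) in Sir3_3xHA.

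By time, the mating genes of Sir3_3xT7 were lower than in wt1 from starvation on, apart from the a-specific list at 5 min, and the a-specific list of Sir3_3xHA was lower at starvation, 5 min and 90 min. The median difference of the 6 a-specific genes other than BAR1 between Sir3_3xT7 and wt1 was 0.76 at midlog (adjusted p = 0.278 with an estimated correlation), -1.61 at starvation (0.0042), -1.54 at 5 min (0.199), -2.77 at 30 min (5.29e-05), -2.59 at 90 min (7.98e-06), -3.04 at 1 doubling (3.91e-06) and -1.12 at 2 doublings (0.0101). For the 12 haploid-specific genes it was -0.13 (0.954), -1.27 (3.14e-05), -0.95 (0.0248), -1.73 (2.66e-07), -1.90 (4.85e-09), -1.75 (1.79e-09) and -0.95 (5.89e-05). In Sir3_3xHA the a-specific medians were 0.20 (0.877), -1.97 (8.19e-05), -1.33 (0.0175), -1.64 (0.0550), -2.13 (2.29e-04), -1.56e-05 (0.994) and 0.32 (0.937). At 30 and 90 min its replicates lay apart, at -3.40 and -0.04 and at -3.43 and -0.35. The a-specific list of Sir3_3xT7 at midlog was higher than in wt1 at the preset correlation (camera adjusted p = 0.0037). BAR1, which wt2 lacks, was left out of this list for every strain. Its centred mean over 14 libraries was 1.02 in wt1, 0.96 in Sir3_3xT7 and 0.92 in Sir3_3xHA.

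**Figure D4:**
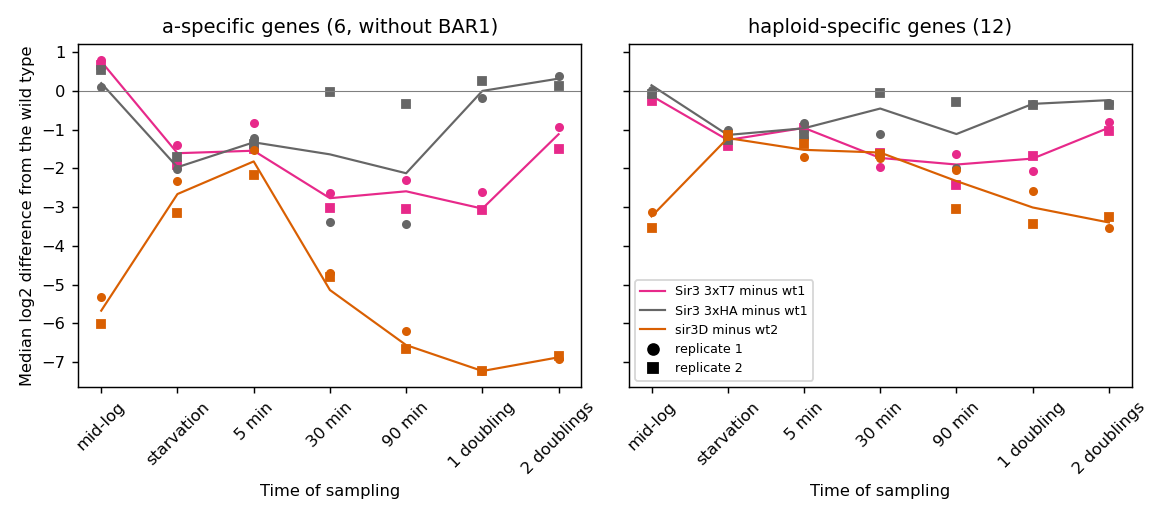
Median centred log2 difference from the wild type of 6 a-specific (left) and 12 haploid-specific genes (right) at each time, in Sir3_3xT7 and Sir3_3xHA against wt1 and sir3D against wt2, with each replicate as a circle or a square. The a-specific median of Sir3_3xT7 is 0.76 at midlog and -3.04 at 1 doubling.

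Averaged over the 7 times, limma called no single gene between the tagged strains (0 called, 24 at an unadjusted p under 0.05). The 24 are also under a share of 0.05 of the 5567 genes, so the lack of calls does not show that the strains are alike. GPA1 lay at -1.03 ± 0.26 in Sir3_3xT7 against Sir3_3xHA, FUS3 at -1.08 ± 0.37, HO at -1.05 ± 0.35 and FAR1 at -1.03 ± 0.29 (adjusted p = 1.00 for each). The haploid-specific list differed (0 of 12 called, 4 fell adjusted over the list alone; median -0.60, 7.69e-22; 0.0111 estimated). All genes correlated between batches at -0.25. At 1 doubling alone GPA1 (-3.02 ± 0.45, 1.87e-05), FUS3 (-3.22 ± 0.56, 5.14e-04) and STE2 (-2.75 ± 0.59, 0.0202) were lower in Sir3_3xT7, out of 7 genes that were looked at by time after the strain comparisons were seen. Time courses after release differed from wt1 for 1 gene in Sir3_3xT7, MF(ALPHA)1, whose change since starvation lay 3.67 above that of wt1 at 30 min and 5.40 at 90 min (adjusted p = 0.0066). It was not called against wt2, with a pseudocount 5 times smaller or with the fill value kept. In Sir3_3xHA it lay 3.50 and 4.14 above (0.668), and 0 genes were called, with 35 at an unadjusted p under 0.05, again under that share. Without replicate 1 the Sir3_3xT7 count was 0 and without replicate 2 it was 12, and the Sir3_3xHA count was 4 without replicate 2.

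The strain with SIR3 under the GAL10 promoter, grown in galactose, differed from the wild types in 507 genes, 242 higher and 265 lower (94 and 179 on the spike-in scale). SIR3 rose by 4.18 ± 0.28 (adjusted p = 2.17e-06) in its 2 series against the 4 wild-type series. The galactose genes GAL2, GAL7 and GAL1 rose by 7.23 ± 0.30 (6.05e-08), 7.23 ± 0.39 (6.32e-07) and 5.86 ± 0.22 (3.18e-08), GAL10 by 7.75 ± 0.39 (3.32e-07) over wild types at 0 in 21 of 28 libraries, the glucose signalling gene MTH1 by 3.78 ± 0.23 (8.42e-07) and JEN1 by 3.69 ± 0.22 (7.84e-07). The glucose transporter genes HXT1 (-5.33 ± 0.30, 7.36e-07) and HXT3 (-4.56 ± 0.32, 3.13e-06), the iron genes FIT3 (-4.56 ± 0.49, 1.53e-04) and FIT2 (-4.14 ± 0.58, 8.31e-04) and PRM7 (-3.91 ± 0.51, 5.02e-04) fell; AIF1 was listed at 0 in all 14 oeSir3 libraries. HMRA1 fell (-3.46 ± 0.44, 4.14e-04). SIR4 lay at 0.47 ± 0.24, SIR1 at 0.46 ± 0.17 and SIR2 at -0.08 ± 0.29, not called. This strain differs from the wild types in background, in sugar and in the deleted MAT and HML loci as well as in SIR3, and these cannot be separated in the comparison. Both of its series also lie in the shared batch, while replicate 1 of each wild type lies in the other.

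In oeSir3 SIR3 was low and HMRA1 high at starvation and 5 min, and the reverse at midlog and at the doublings; the relation was not tested. The centred log2 level of SIR3 was 3.90 at midlog, 0.80 at starvation, -0.02 at 5 min, 1.16 at 30 min, 3.39 at 90 min, 4.28 at 1 doubling and 4.16 at 2 doublings, as means of 2 libraries. That of HMRA1 was -5.57, 4.86, 4.17, 3.17, 1.59, -4.09 and -5.03, with 1 of 2 libraries at 0 at midlog and at 2 doublings. GAL1 went from 6.58 to -0.50 at starvation, -1.73 at 5 min and 6.84 at 1 doubling.

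**Figure D5:**
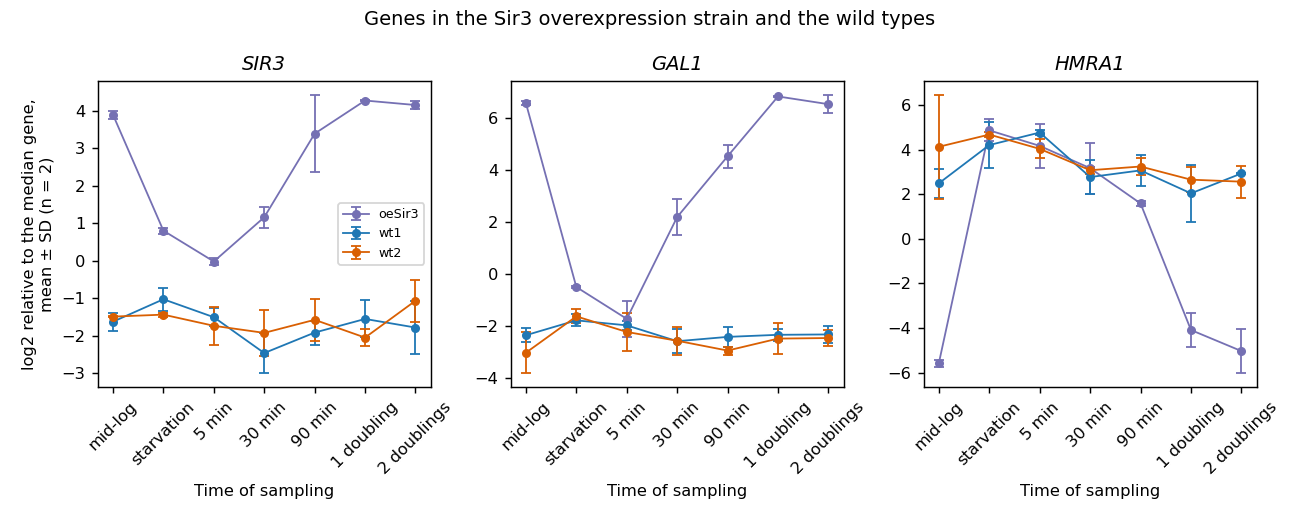
Centred log2 level of SIR3, GAL1 and HMRA1 by time in oeSir3, wt1 and wt2, as the mean and SD of 2 libraries. In oeSir3 SIR3 goes from 3.90 at midlog to 0.80 at starvation while HMRA1 goes from -5.57 to 4.86.

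By gene list, all 8 galactose genes rose in oeSir3 (median 4.73, camera adjusted p = 2.59e-15; adjusted p = 0.158 with an estimated correlation). Glycolysis had 12 falls of 17 (13 adjusted over the list alone; median -2.17, 1.54e-10; 0.222 estimated), with PDC1 at -2.80 ± 0.32 (2.24e-04) and PGK1 at -2.57 ± 0.30 (2.49e-04), and ribosomal proteins 37 of 103 (62 adjusted over the list alone; median -1.31, 1.90e-16; 0.353 estimated). The iron regulon had 9 falls of 17 (13 adjusted over the list alone; median -1.75, 7.53e-11; 0.222 estimated), purine genes 4 of 10 (median -0.93, 5.32e-06; 0.222 estimated) with ADE17 at -2.68 ± 0.30 (1.88e-04), and pheromone-response genes 5 of 13 (6 adjusted over the list alone; median -0.74, 0.0043; 0.222 estimated). TCA cycle genes had 6 rises of 13 (median 0.92, 2.05e-04; 0.30 estimated), with SDH2 at 2.65 ± 0.43 (0.0022), mitochondrial ribosomal genes 9 of 41 (10 adjusted over the list alone; median 0.70, 3.48e-09; 0.222 estimated), fatty acid oxidation genes 5 of 11 (median 0.87, 2.40e-04; 0.222 estimated) and gluconeogenesis genes 6 rises and 2 falls of 18 (median 0.39, 0.0274; 0.551 estimated), with the alcohol dehydrogenase gene ADH2 at 2.61 ± 0.30 (2.33e-04). No list was called with an estimated correlation. Genes near an end had medians of -0.30 within 5 kb, -0.14 from 5 to 10 kb and -0.08 from 10 to 20 kb, and the 37 within 10 kb a median of -0.20 (0.0519; 0.633 estimated), with COS12 at -1.27 ± 0.31 (0.0201). The median within 10 kb was called without oeSir3 replicate 1 (-0.29), wt1 replicate 2 (-0.39) or wt2 replicate 2 (-0.38), and not without oeSir3 replicate 2 (-0.08), wt1 replicate 1 (-0.10) or wt2 replicate 1 (-0.05). The markers URA3, LEU2 and MET17 were detected here and listed at 0 in the other 7 strains.

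All 507 genes moved in the pooled direction within the shared batch, 375 of them by 2-fold or more; neither oeSir3 series lies in the other batch. The count was 212 without oeSir3 replicate 1, 319 without oeSir3 replicate 2 and 781 without wt2 replicate 2. The response to release differed from wild type for 2477 genes, with fewer called on the spike-in scale and more with a replicate block. GCY1, a galactose-inducible reductase gene, lay 9.64 above wild type at 1 doubling in its change since starvation (adjusted p = 1.45e-31), GAL1 8.05 (3.24e-23), GAL2 10.55 (2.43e-22) and GAL7 10.85 (1.21e-20), and the respiratory genes QCR2 and ATP2 6.39 (2.43e-22) and 6.81 (1.21e-20). Without replicate 1 the count was 1321 and without replicate 2 it was 1366.

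The wild types differed in 4 genes, 1 higher and 3 lower in wt1. BAR1, the alpha-factor protease, was listed at 0 in all 14 wt2 libraries and had 41.5 to 389 reads in wt1, although the labels describe a disrupted BAR1 in both. LYS2 was listed at 0 in all 14 wt1 libraries and in those of both tagged strains, and had 9.0 to 114.0 reads in wt2. TRP1 fell (-3.84 ± 0.37, adjusted p = 6.03e-04) and the chaperone-binding gene SNL1 (-2.51 ± 0.38, 0.0414). All 4 moved in the pooled direction by 2-fold or more in both batches, and 200 genes were called without wt2 replicate 2. Of 38 lists 7 were called at the preset correlation, among them ribosomal proteins (median -0.78, 1.67e-15; adjusted p = 0.943 with an estimated correlation), and none with an estimated one.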

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

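The tests of the sir2D library, those of the tagged strains, and the centred splits for starvation and 5 min were chosen only after the result was seen.

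Among groups of 4 wild-type libraries, 6 of 151 held a library far from the other 3 (3.97%, where chance gives about 5%). At starvation the spike-in level of the median gene was -2.79 in wt2 replicate 1 and between -1.85 and -1.71 in the others. INA1 at midlog lay at -0.11 in wt2 replicate 1 (others 3.15 to 3.66), PHO84 at midlog at 2.27 in the same series (others 5.23 to 5.53), and AAH1 at 90 min at 1.37 (others 2.62 to 2.83). MLS1 at 90 min lay at -3.76 in wt2 replicate 2 (others -4.45 to -4.37). ACS1 at 1 doubling was detected in wt2 replicate 1 at -4.55 and listed at 0 in the other 3 libraries.

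The response to release differed between strains by the F test for 10 genes in sir3D, 9 in sir2D, 6 in sir4D, 1 in Sir3_3xT7 and 2477 in oeSir3 (limma). In sir3D the adjusted p was 3.15e-06 for GPA1, 4.41e-06 for HO, 7.49e-06 for STE2, 1.11e-05 for STE6, 1.68e-04 for FAR1 and 0.0346 for SCC4. In sir2D it was 2.69e-07 for FAR1 and HO, 1.26e-06 for STE2, 1.73e-06 for GPA1 and STE6, and 7.23e-04 for SIR2, which is listed at 0 in sir2D. In sir4D it was 3.13e-07 for HO, 4.74e-06 for STE2, 1.65e-05 for FAR1, 2.48e-05 for STE6, 4.18e-05 for GPA1 and 0.0032 for FUS1. MF(ALPHA)1 differed in Sir3_3xT7 at 0.0066. In oeSir3 it was 1.45e-31 for GCY1, 3.24e-23 for GAL1, 2.43e-22 for GAL2 and QCR2, and 1.21e-20 for ATP2 and GAL7.

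The sir2D library labelled 1 doubling, replicate 1, lay close to the 90 min library of its series. The robust SD of their log2 ratio was 0.154, the lowest of 392 pairs of libraries (next 0.184), and between 0.519 and 1.07 for the same pair of times in the 15 other series. One RNA sample or library under both labels is a candidate explanation. A culture slower than the others at its first doubling cannot be told apart from it, since the labels give no minutes for a doubling; the library's correlation across genes with the 90 min profile was 0.239 above that with the 1 doubling profile.

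More genes were called against wt2 when its replicate 1 was the only reference, 150 against 29 in sir3D, 139 of them lower. The coding length of the called genes had a median of 372 bases, against 1242 for all genes. A processing batch as the cause is argued against by wt1 replicate 1, of the same batch, against which sir3D had 24 calls, fewer than the 34 against both wt1 series. A trend with gene length in wt2 replicate 1 may account for part: with the trend removed 48 genes were called against it and 33 against both series. That stays open, since 48 lies close to the limit of 1.5 times set for the test. No biological explanation was tested.

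The a-specific and haploid-specific lists were lower in Sir3_3xT7 than in wt1 at most times from starvation on and were not called lower at midlog. At midlog the a-specific list was higher by camera at the preset correlation alone (median 0.76, adjusted p = 0.0037, and 0.278 with an estimated correlation). RNA of wt2 or of a deletion strain in these libraries is argued against by LYS2, at 0 percent of its wt2 level in each Sir3_3xT7 library. A processing batch is argued against by a median difference of the 18 list genes of -1.71 in the batch where it was nearer to 0 and -1.93 in the other. Alpha information from the silent cassette, the explanation the impaired Sir3 would give, cannot be told apart, since HMLALPHA1 and HMLALPHA2 had 0 values above the fill value in every strain, deletions included. The pattern may be biological, as a hypothesis found and tested on the same data.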

How the results depend on the processing

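Of 578 values of the comparisons under alternatives, 427 kept their direction and their side of the threshold or lay within 1.5 times the count, and of 2496 values of named genes and lists 2357 did, 136 lost and 3 gained a call. The cause was not tested except where stated. The fill value kept, the doubted libraries, the batch block, 1 batch alone, the length trend, the split wt2 series, the estimated correlation and leave-outs within 10 kb, and the leave-outs of subtelomeric medians were chosen after seeing the data.

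With a pseudocount 5 times larger the response count was 4 in sir3D, and sir3D against wt2 had 4 calls at starvation and 7 at 5 min, Sir3_3xT7 had 3, Sir3_3xHA 0 and oeSir3 286. With one 5 times smaller the response counts were 16 in sir3D and 0 in Sir3_3xT7, and sir3D had 57 calls at midlog, 55 at starvation and 73 at 5 min. By adjusted p alone oeSir3 had 827. With the fill value kept, response counts were 6 in sir3D and 0 in Sir3_3xT7, sir3D had 19 calls at midlog, 45 at starvation, 9 at 5 min, 12 at 30 min, 16 at 90 min and 21 at 2 doublings, and wt1 against wt2 had 2.

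On the centred scale the wild-type counts were 2451 at starvation, 1089 at 5 min, 2557 at 1 doubling and 2563 at 2 doublings. On the spike-in scale Sir3_3xT7 had 2 calls, Sir3_3xHA 1 and oeSir3 273, the response counts were 3 in sir2D, 1 in sir4D and 1503 in oeSir3, and sir3D had 18 calls at midlog, 6 at starvation, 14 at 5 min and 23 at 2 doublings. With wt1 alone the counts were 88 at 5 min, 1924 at 30 min and 2204 at 90 min, and in the batch with separate fill values 2429 at starvation, 88 at 5 min, 1588 at 30 min and 1889 at 90 min; these use fewer libraries.

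With single libraries in place of series means the counts were 132 in sir3D, 171 in sir2D, 230 in sir4D, 34 in Sir3_3xT7, 13 in Sir3_3xHA, 5 between the tagged strains and 157 between the wild types; such a fit treats the 7 times of a series as independent. Against the other wild type Sir3_3xT7 had 10 and Sir3_3xHA 6, and response counts were 13 in sir4D, 0 in Sir3_3xT7 and 2 in Sir3_3xHA. With a batch block the counts were 50 in sir3D, 44 in sir2D and 18 in Sir3_3xT7, the sir4D response count was 10, and sir3D had 54 calls at midlog, 32 at starvation, 125 at 5 min and 55 at 30 min. Without the 12 doubted libraries the sir3D response count was 4, sir3D had 21 calls at midlog, 6 at starvation, 7 at 5 min, 62 at 30 min and 22 at 2 doublings, and Sir3_3xHA had 1.

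Replicate numbers were not taken as pairs, since not every pair of groups deviated together: of 1372 pairs of groups 854 had a correlation of replicate differences over 0.1 and 129 under -0.1 (median 0.22, range -0.48 to 0.75). Among wt1, wt2, the tagged strains, sir2D and sir3D, whose replicates 1 and 2 lie in different batches, the medians by pair of strains were 0.17 to 0.55, and with oeSir3 or sir4D, whose replicates share a batch, -0.11 to 0.14. With a replicate block the response counts were 58 in sir3D, 28 in sir2D, 34 in sir4D, 1 in Sir3_3xHA and 3854 in oeSir3, with all 10, 9 and 6 genes called in the deletions without it among them, and sir3D had 26 calls at starvation and 70 at 5 min.

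Leaving out 1 series at a time, where the lone series left is assumed to vary like the others, gave 205 to 584 genes at 5 min, 1995 to 3236 at 30 min and 2270 to 3308 at 90 min. It gave 16 to 150 in sir3D, 19 to 202 in sir2D, 22 to 297 in sir4D, 0 to 4 in Sir3_3xT7, 0 to 3 in Sir3_3xHA, 212 to 781 in oeSir3 and 3 to 200 between the wild types. Response counts were 4 to 29 in sir3D, 5 to 11 in sir2D, 0 to 12 in Sir3_3xT7, 0 to 4 in Sir3_3xHA and 1321 to 1366 in oeSir3. For sir3D by time they were 21 to 947 at midlog, 2 to 344 at starvation, 8 to 293 at 5 min, 15 to 275 at 30 min, 17 to 620 at 90 min, 18 to 25 at 1 doubling and 20 to 95 at 2 doublings. Subtelomeric medians ranged from -0.0436 to 0.36 in sir3D, -0.0393 to 0.31 in sir2D, -0.13 to 0.22 in sir4D, 0.0687 to 0.39 in Sir3_3xT7, 0.0741 to 0.34 in Sir3_3xHA and -0.27 to -0.0060 in oeSir3; the oeSir3 median passed the test without wt1 replicate 2, at -0.16.

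With an estimated correlation 46 of 284 list calls held, and the subtelomeric medians of 0.13 in sir3D and sir2D, -0.0141 in sir4D, 0.18 in Sir3_3xT7 and 0.16 in Sir3_3xHA were no longer called. With a processing batch block the sir4D median was 0.20 and called, while that of oeSir3 went from -0.0871 to -0.0178 and was called with neither model. Within 30 kb the sir3D median was 0.0296 and not called. Within 10 kb the medians of 0.45 in sir3D, 0.52 in sir2D and 0.38 in sir4D were not called with an estimated correlation, and that of oeSir3 was called without oeSir3 replicate 1 (-0.29), wt1 replicate 2 (-0.39) and wt2 replicate 2 (-0.38), and not without oeSir3 replicate 2 (-0.0791), wt1 replicate 1 (-0.10) and wt2 replicate 1 (-0.0458). With wt1 as reference the correlation across genes was 0.72 between sir2D and sir3D and 0.62 between sir3D and sir4D. With the wt2 series split between comparisons it was -0.0127 (sir2D and sir3D, reversed), 0.10 (sir2D and sir4D) and 0.0324 (sir3D and sir4D), and within batches 0.24, 0.31 and 0.29.

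Each time comparison was set against all 35 splits of its 8 wild-type libraries into 4 and 4. For starvation against midlog 2 splits gave as many genes on the spike-in scale (4232 real, 4238 highest other). The other of these set wt2 replicate 1 at midlog with wt1 replicates 1 and 2 and wt2 replicate 1 at starvation. It holds most of the real contrast, so the test cannot decide there. On the centred scale only the real split, 1 of 35, gave as many (2445 and 1284). For the other comparisons 1 split, the real one, gave as many. With 35 splits 1 of 35 is the lowest share possible, so the test does not exclude chance. The counts were 637 against 295 at 5 min, 3269 against 2131 at 30 min, 3484 against 2100 at 90 min, 4071 against 3164 at 1 doubling and 4135 against 2742 at 2 doublings. Centred, these were 1080 and 586, 2569 and 1480, 2422 and 1207, 2554 and 1151, and 2561 and 1245. The split by batch called 569 at 5 min on the centred scale.

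Smaller changes were called less often; how far depth or replicate spread sets this was not tested. In simulated data 4 of 50 genes changed by 1 on the log2 scale were called in the starvation comparison, 24 of 50 changed by 2 and 45 of 50 changed by 3; for sir3D against wt2 these were 12, 47 and 49.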

Other observations

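All tests in this part were chosen only after the result was seen; that of Sir3_3xT7 against Sir3_3xHA at 1 doubling was written down after the difference of each strain from wt1 had been seen.

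MF(ALPHA)1, the gene for alpha-factor, was higher in both tagged strains at 90 min. It rose by 4.43 ± 0.72 over wt1 in Sir3_3xT7 (adjusted p = 7.15e-05; replicates 4.18 and 4.68) and by 3.60 ± 0.72 in Sir3_3xHA (0.0103; 4.03 and 3.17). MF(ALPHA)2 lay at 3.58 ± 0.95 (0.0960) and 1.87 ± 0.95, not called. The other alpha-specific genes were not called either. SAG1 lay at 1.37 ± 0.50 and 1.15 ± 0.50, and STE3 at 0.16 ± 0.49 and 0.48 ± 0.49. Replicate 2 of STE3 was slightly below wt1 in both strains (-0.08 and -0.21). The median of the 4 alpha-specific genes was 2.47 and 1.51 (3.33e-06 and 5.19e-06 with an estimated correlation). At midlog it was 0.79 (0.0287) and 1.34 (8.62e-04), with MF(ALPHA)1 at 2.40 ± 0.72 and 2.58 ± 0.72, not called; against wt2 at midlog the list was not called (0.767 and 0.660). At the other times it was not called against wt1 with an estimated correlation. Against wt2 the medians at 90 min were 2.35 (2.24e-05) and 1.38 (0.0136), with MF(ALPHA)1 at 3.62 ± 0.72 (0.0026) and 2.78 ± 0.72 (0.0649). In the deletions at 90 min MF(ALPHA)1 lay at -0.50 ± 0.72 (sir2D), 0.17 ± 0.72 (sir3D) and -1.42 ± 0.72 (sir4D) against wt2, not called. The 90 min libraries of Sir3_3xT7 lay far apart in the spike-in level of the median gene, at -2.41 in replicate 1 and 1.21 in replicate 2. In replicate 1 the slope with coding length was -0.36.

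The mating lists of the tagged strains fell relative to wt1 between midlog and starvation. At midlog the a-specific median of Sir3_3xT7 lay 0.76 above wt1 and that of Sir3_3xHA 0.20. In Sir3_3xT7 the change of the difference was -2.78 for 6 a-specific genes and -1.17 for 12 haploid-specific genes, and the higher of both adjusted p values with an estimated correlation was 0.0032. In Sir3_3xHA it was -2.40 and -1.11 (6.47e-04). At 1 doubling Sir3_3xT7 lay below Sir3_3xHA by list medians of -3.08 and -1.55 (5.31e-08). The a-specific median of Sir3_3xHA was -1.56e-05 and 0.32 at 1 and 2 doublings. No explanation was tested here.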
